A study of Brugia malayi with 8 samples.

How the data were processed

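RNA from whole Brugia malayi larvae was measured on 8 two-channel oligonucleotide arrays, 1 per time point. Brugia malayi is a filarial nematode that causes lymphatic filariasis, and L3 and L4 are the third and the fourth of its larval stages. Per the labels, L3 larvae were cultured for up to 10 days, ascorbic acid was added on day 5 at a stated final concentration of 75 mM (a unit in doubt, since 75 uM may have been meant), and molting was seen by day 8 or 9. Per the labels, the Cy3 channel of every array held RNA of uncultured L3 larvae as a common reference and the Cy5 channel held RNA of the time point, with no dye swap. The sources used here do not say whether all 8 reference samples came from a single pool of larvae.

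Per the labels, total RNA of pooled larvae was copied with random primers and labelled with dye-carrying dendrimers. The deposited scanner files hold spot intensity values in both channels, foreground and local background, not normalized, read with GenePix Pro 6.0.1.26, per the file headers. They also hold the percent of saturated pixels per spot and a flag for spots the software did not find, per the file headers. The authors' value table of the series holds log2 values whose normalization is not given in the sources used here. Set against the scanner values, it ran from -1.10 to -1.06 per log2 unit for bright spots, so that its direction is L3 over time point. Its column medians, in the order of the time points, were -0.0205, -0.014, -0.0531, -0.107, -0.0604, -0.0674, -0.00595 and -0.0182, so that the arrays were centred near 0, by a method that stays unknown. It was used, with its sign turned, only as an alternative.

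Each array carried 37632 spots, of which 36208 belonged to 18104 probes, mostly 2 spots each, 1384 were empty and the rest held 10 control oligonucleotides. Backgrounds were corrected with normexp at an offset of 50, and the log2 ratio of Cy5 over Cy3 was normalized within each array by loess, in limma 3.58.1 under R 4.3.3. Control and not-found spots had weight 0 in loess and were left out, and the spots of a probe were averaged. A probe was tested if the foreground exceeded the local background by 2 background standard deviations in either channel on at least 3 arrays, which held for 5896 probes. Where a channel was not above background, a floor fold was taken: the brighter channel against the lowest signal of probes above background in the other, or its own signal if higher. Probes not above background can lie over that lowest signal, so that a floor fold is not a strict lower limit. With its own signal the fold is only the measured ratio, and it is named so below. These channel values were taken after loess and quantile scaling of the mean intensities between arrays, and they stay open to dye bias.

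The percent of probe spots found ran from 59.9 to 80.4, and probes above background numbered 3307 to 6245 in Cy5 and 2271 to 2991 in Cy3. A typical standard deviation between the spots of a probe was 0.28 to 0.35 on the log2 scale. The single array per time point limits the precision, and comparisons of single arrays carry no p-value. The difference between the 5 arrays after and the 3 arrays before ascorbic acid, and the slope over days, were fitted with limma and adjusted by the Benjamini-Hochberg method at a threshold of 0.05. For the slope, the molting array stood at day 8.5. Time points within a phase are not replicates, so the residual spread of both fits includes change over time.

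Tests were checked on simulated ratios for the 5896 probes with 200 probes changed. For the phase difference, 26.0% of changes of log2 1, 62.0% of log2 2, 86.0% of log2 3 and 98.0% of log2 4 were recovered, with 13 wrong calls. For the slope, 48.0% of changes of 0.20 per day and 90.0% of 0.40 per day were recovered, with 6 wrong calls. With no change simulated, both gave 0 calls. For a quadratic day term, 8.0% of changes of size 1, 64.0% of size 2, 94.0% of size 4 and 100.0% of size 6 were recovered, with 5 wrong calls and 0 with no change simulated.

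No probe was given a gene name: 0 of 18095 probe names matched the table of reference genes for this species, and apart from these names the files do not pair probes with genes. The names of 9241 probes have the form of numbered gene models, which could not be resolved to genes here. Probes are therefore printed by the name the files give or, where that name begins with a digit, by the identifier in the same files (BMX and a number), at most 2 higher and 2 lower per comparison. They were taken by size from the rule for named genes, written before the data were examined, which asked for more. Of 34 gene lists fixed at the same time, 1 matched any probe. That list holds 804 probes whose names begin with Wbm, the prefix of gene tags in the genome of Wolbachia, the bacterial endosymbiont of this worm. The files do not state a probe's organism.

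Alternatives were other background corrections, median centring, looser and stricter filters, keeping not-found spots, the authors' values, scaling between arrays, Cy5 alone, array weights, leaving out each array, the order of time points in place of days, and 3 against 3 arrays. Added after the data were seen were the date in the file header as a block, the 6 arrays of a single header date, probes measured on all arrays, and a quadratic day term. The array from 3 h and that from 24 h at 37C share a header date, and the other 6 share another. The sources used here do not state whether this date marks the scan or only the reading of the spots, so that it may not mark a batch of hybridizations.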

Results

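The study followed gene expression in Brugia malayi larvae through the molt from L3 to L4 in culture. The 8 time points were 3 h, 24 h and 5 days at 37C, then 3 h, 24 h and 48 h after ascorbic acid was added, molting larvae, and L4 larvae of day 10. Each was measured on 1 array against uncultured L3 larvae, without replicates or a dye swap. The percent of probe spots found was 59.9 and 70.7 on the arrays of 3 h and 24 h at 37C and 80.4 at 5 days. It was 73.2, 80.3 and 77.5 after 3 h, 24 h and 48 h of ascorbic acid, and 61.8 on both the molting and the L4 array. All ratios are time point over L3, opposite to the authors' value table.

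The first comparison asked how far each time point lay from the L3 larvae. Transcripts at probes BMC11985 and BMW00290.540, bright in L3 larvae, were at the low end of the range from day 5 onwards. BMC11985 had a log2 ratio of -1.17 after 3 h and -4.28 after 24 h. At 5 days its measured signal was 142-fold lower than in L3, with Cy5 not above background. In L4 larvae it was 103-fold lower by the floor fold. BMW00290.540 had a log2 ratio of 0.25 after 3 h and -2.40 after 24 h, and was 122-fold lower at 5 days by the floor fold. On the molting array its spots disagreed, with a standard deviation of 3.04 around -4.64.

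At the high end stood BMX7677 and BMC02256, dim in the L3 channel. BMC02256 had a log2 ratio of -0.34 ± 0.20 (SD of 2 spots) after 3 h and a measured signal 41.1-fold higher than L3 after 24 h. Its measured signal was 119-fold higher after 3 h of ascorbic acid, and in molting larvae it was 55.4-fold higher by the floor fold. Its L3 channel was above background on the array of 3 h at 37C only, so that none of these folds is a lower limit. BMX7677 was 45.9-fold higher at 5 days and 113-fold higher after 3 h of ascorbic acid by the floor fold. Its 2 spots differed on these arrays, with an SD of 1.97 and 0.98 on the log2 scale. None of these probes could be given a gene name.

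**Figure D1:**
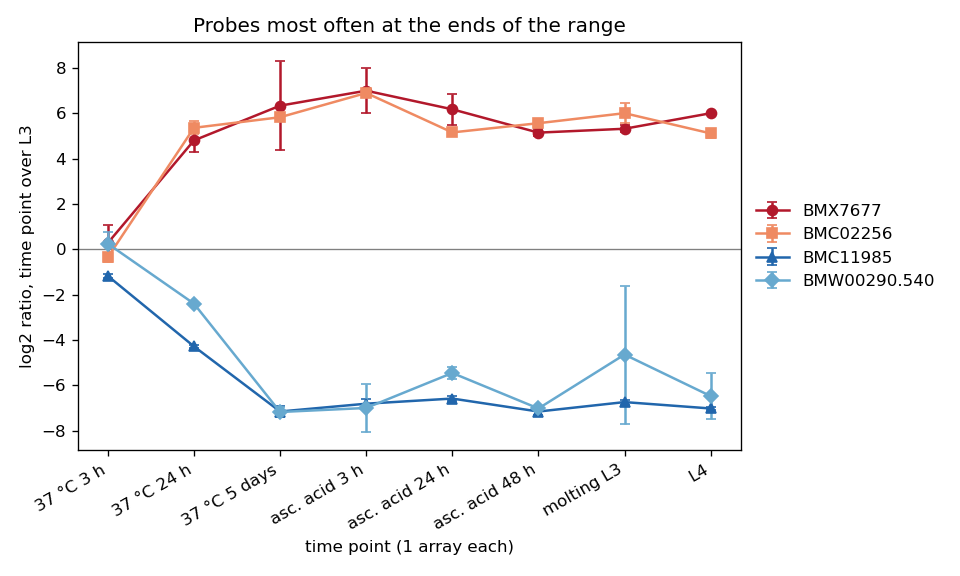
Log2 ratio of time point over L3 (vertical axis) at the 8 time points in order (horizontal axis) for 2 probes often among the highest and the 2 most often among the lowest (of 3 probes among the highest on 3 arrays each, the 2 with the larger peak ratios); bars are the SD between the spots of a probe on 1 array. BMC02256 goes from -0.34 to 5.36 between 3 h and 24 h at 37C, and BMC11985 from -1.17 at 3 h to -7.15 at 5 days.

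After 3 h at 37C, 301 of 5591 measured probes were at least 2-fold higher than in L3 larvae and 265 at least 2-fold lower. After 24 h the counts were 761 and 490, and after 5 days 1153 and 433. With 3 h, 24 h and 48 h of ascorbic acid, 1124, 1021 and 1131 probes were higher and 473, 496 and 474 lower. In molting larvae 765 were higher and 577 lower, and in L4 larvae 1016 and 573. Of the higher probes, 203, 608, 963, 965, 776, 868, 597 and 772 had Cy3 not above background, in the order of the time points. Most higher ratios were therefore taken against a dim L3 signal. The changed probes made up 10.1% of those measured at 3 h, 21.5% at 24 h and 23.8% to 27.7% from 5 days on. Noise between the spots of a probe alone passed 2-fold for 0.57% to 1.83% of probes. At least 16-fold lower were 0 probes at 3 h, 9 at 24 h, 44 at 5 days and 31 in L4 larvae.

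The balance of higher and lower probes depended on scaling and filtering. Of the changed probes, 53.2%, 60.8%, 72.7%, 70.4%, 67.3%, 70.5%, 57.0% and 63.9% were higher in the order of the time points. Median centring put the shares at 46.2%, 81.7%, 90.5%, 92.5%, 87.2%, 89.2%, 61.1% and 86.1%, and the authors' values at 68.0%, 83.7%, 93.9%, 94.4%, 92.3%, 93.6%, 65.1% and 87.4%. Among the 1395 probes above background in both channels on every array, most changed probes were lower from 24 h on, with 29.8% higher at 24 h, 36.9% at 5 days, 27.8% in molting and 41.7% in L4 larvae. The median log2 ratio of the tested probes was up to 0.24 here, up to 0.80 with median centring and up to 1.43 in the authors' values. The control oligonucleotides had median log2 ratios from 0.56 to 2.87 between arrays, so that each ratio is relative to the centre of its own array.

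**Figure D2:**
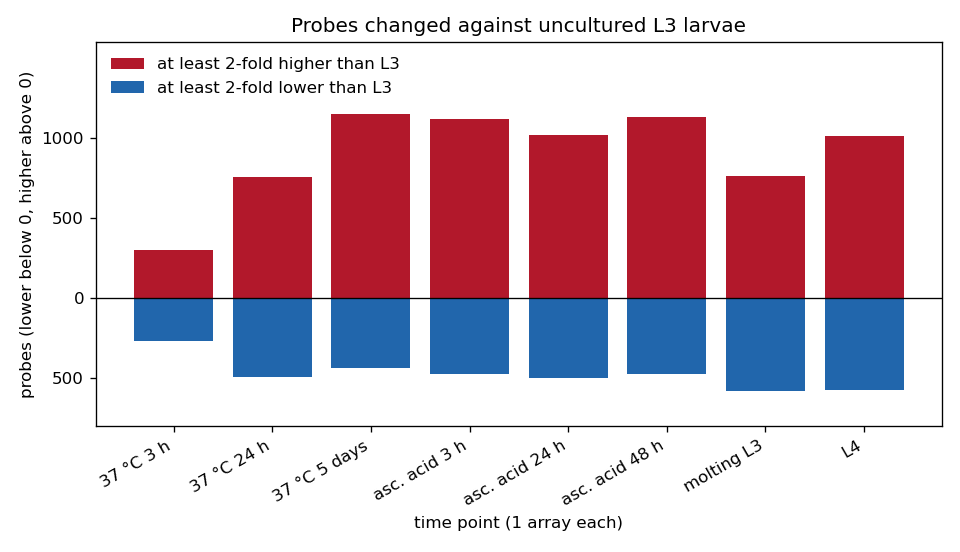
Number of probes (vertical axis) at least 2-fold higher (above 0) or lower (below 0) than L3 larvae at each time point (horizontal axis), 1 array each. The changed share goes from 10.1% at 3 h to 27.7% in L4 larvae; among probes above background in both channels on all arrays, not drawn here, most changed probes were lower from 24 h on.

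Many probes kept their direction. Of 5438 probes measured on all 7 arrays from 24 h on, 115 were at least 2-fold lower on all 7 and 112 at least 2-fold higher on all 7. Unchanged samples simulated against a shared reference gave 6.26 and 6.03 on average over 100 simulations. Their noise had the variance of the ratios at 3 h at 37C, 0.41. The standard deviation of the ratios over probes was 0.64 at 3 h and 0.88 to 1.21 on the other arrays, a wider spread than was simulated. Between 24 h at 37C and L4 larvae, 300 lower and 429 higher probes were shared, where independent lists would share 48.6 and 130.0 and unchanged samples simulated against a shared reference 87.8 and 89.5, and 21 went opposite ways. Part of the excess may come from the shared reference. Without a dye swap, any dye bias of a probe would also repeat in the same direction on every array. The simulation, with its narrower spread and no dye bias, cannot size either part.

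Over probes, which are not independent replicates, the arrays of days 5 to 7 correlated with each other at r = 0.71 to 0.84. Molting and L4 larvae correlated at 0.77. Both correlated with 24 h at 37C at 0.69 to 0.70, and with the arrays of days 5 to 7 at 0.43 to 0.61. The array of 3 h at 37C stood apart at 0.22 to 0.41. The arrays of days 5 to 7 were also those with the most probe spots found, 73.2% to 80.4%, against 59.9% to 70.7% on the others. Array-wide signal and time in culture therefore cannot be told apart in these blocks. Unchanged samples sharing a reference, with equal noise in both, have an r of 0.50 by construction. With the noise set from the array of 3 h at 37C, their covariance is likewise fixed at 0.20, so that neither value tests anything. The observed covariances were 0.15 to 1.10. The signal levels of every pair of arrays correlated at 0.92 to 0.95 in the L3 channel alone and at 0.74 to 0.92 in Cy5 alone. As correlations of levels, these cannot be set against those of the ratios.

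**Figure D3:**
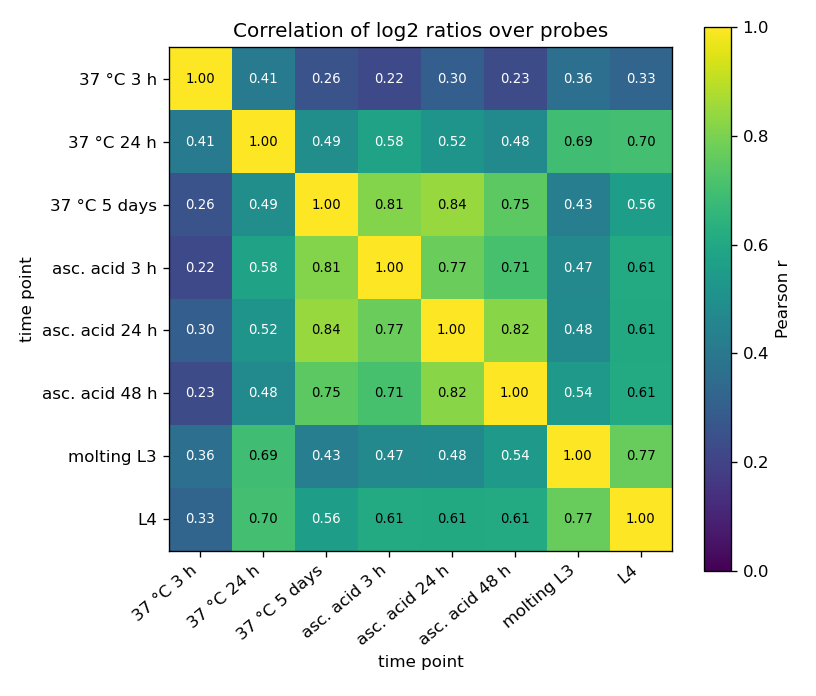
Pearson correlation of log2 ratios over probes for each pair of time points, shown by colour and number, with time points on both axes. The 4 arrays of days 5 to 7 form a block at 0.71 to 0.84, and 3 h at 37C lies lowest, at 0.22 to 0.41. The arrays of that block also had the most probe spots found.

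Successive time points were then compared for the size of each step. The largest differences lay at BMC06615 and at BMX4784 and BMX4783. BMC06615 went from a log2 ratio of -3.83 after 48 h of ascorbic acid to 5.16 in molting larvae and 1.76 in L4 larvae. BMX4784 went from -2.61 after 24 h at 37C to 5.67 at 5 days, and to -2.90 after 3 h of ascorbic acid on the same culture day. BMX4783 went from 5.06 at 5 days to -2.88 after 3 h of ascorbic acid. Part of each change lay in the L3 channel, which moved the opposite way: by -1.87 log2 and then 1.57 at BMC06615, not above background in it on the molting array, by -2.42 and 2.32 at BMX4784, and by 2.31 at BMX4783, not above background in it at 5 days. Cy5 alone moved by 7.12 and -1.82, by 5.86 and -6.25, and by -5.62. BMX4784 and BMX4783 rose again, to 4.63 and 5.04 after 24 h of ascorbic acid, and stood at 2.89 and 2.95 after 48 h. Both are among the 33 probes, described below, that swung down, up, down and up over the first 5 arrays.

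From 3 h to 24 h at 37C, 610 probes were at least 2-fold higher and 391 lower. From 24 h to 5 days they numbered 875 and 452. Against the 5-day array, 3 h of ascorbic acid gave 260 higher and 347 lower, 24 h gave 261 and 339, and 48 h gave 417 and 396. From 48 h of ascorbic acid to molting larvae, 534 were higher and 924 lower, and from molting to L4 larvae 468 and 355. The step into molting took in 25.9% of probes, the most among these steps, and the step from 5 days to 3 h of ascorbic acid 10.3%.

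The common L3 channel, taken alone and including spot differences that a ratio cancels, passed 2-fold for 606 probes between the 5-day array and that of 3 h of ascorbic acid, where the ratio passed for 607. For the step into molting it passed for 480, against 1458 for the ratio. Among the 1395 bright probes, the ratio passed 2-fold for 46 probes at 3 h of ascorbic acid and 325 at the step into molting. The L3 channel alone passed for 132 and 105 of them. The higher shares of the 7 steps, 60.9%, 65.9%, 42.8%, 43.5%, 51.3%, 36.6% and 56.9%, were 80.9%, 75.2%, 55.1%, 41.6%, 53.1%, 13.5% and 87.5% with median centring. In the authors' values they were 75.0%, 75.8%, 54.6%, 32.8%, 48.1%, 12.4% and 87.8%. Among the bright probes they were 22.3%, 54.9%, 43.5%, 58.9%, 61.9%, 37.8% and 65.7%, so that at the step from 3 h to 24 h at 37C most changed probes were lower, 129 against 37 higher.

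The arrays after ascorbic acid were compared with those before it. The limma fit called 1 of 5896 probes: BMX8314 was lower after, with a fitted log2 difference of -4.74 ± 0.41 (SE) and an adjusted p of 0.0346. It was above background in Cy5 on both measured arrays before ascorbic acid, from 1 spot each, and on 0 of the 4 measured after it. In Cy3 it was above background on 1 array. Against the same kind of floor in Cy5, the Cy5 signal before was 6.60-fold higher, which is not a strict lower limit. The arrays that measured it before were those of 3 h and 24 h at 37C, which share a header date, so that for this probe phase and date cannot be told apart. Of 17 alternatives that tested this probe, 4 called it. Among these 4 were no filter and leaving out the 5-day array or that of 3 h of ascorbic acid. They left its values unchanged, since neither array measured it. In the other 13 the direction held, with a difference of -3.31 to -12.45 and an adjusted p of 0.0659 to 0.943. With not-found spots kept it did not enter the tests. The number of calls was 5 without the 5-day array, 2 without that of 3 h of ascorbic acid, and 0 without any other array. At an unadjusted p under 0.05 stood 260 probes, where 295 are expected by chance. BMW00014.430 differed by -3.59 ± 1.21 and BMC06994 by 3.66 ± 1.60, neither past the threshold (adjusted p of 0.955 for both). BMC06994 was above background in Cy5 on 4 of 7 arrays and in Cy3 on 0, and its difference ran from 2.68 to 7.21 over the alternatives, the highest in the authors' values. Without the 5-day array BMW00014.430 differed by -5.48 and was called (adjusted p of 0.0216), and without that of 3 h at 37C it differed by -2.05. With the header date as a block, and within the 6 arrays of a single date, it differed by 0.18, in the other direction. Its adjusted p ran up to 1.00 over the alternatives. With the header date as a block, which leaves no phase test for BMX8314, the fit called 0 probes (182 at an unadjusted p under 0.05), and within the 6 arrays of a single date also 0 (182). The other date holds arrays before ascorbic acid only. Phase and time in culture cannot be told apart in this design.

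No probe had a slope over days past the threshold in the limma fit, and the smallest adjusted p was 0.0917, for BMC02493 at 0.33 ± 0.04 log2 per day. This probe was above background in Cy5 on 6 of 8 arrays and in Cy3 on 0. At an unadjusted p under 0.05 stood 491 probes, 309 with a positive and 182 with a negative slope, where 295 are expected by chance. The steepest slopes were 1.14 ± 0.28 per day at BMC06939 and -0.66 ± 0.13 at BMW00014.430, not past the threshold (adjusted p of 0.394 and 0.302). BMC06939 was above background in Cy5 on 3 of 6 arrays and in Cy3 on 0, and its slope was 0.45 with not-found spots kept and 3.07 with plain subtraction. That of BMW00014.430 was -0.07 with the header date as a block and -0.01 within the 6 arrays of a single date. With the header date as a block, 15 positive and 28 negative slopes passed, and within the 6 arrays of a single date 2 and 17. Leaving out the L4 array gave 1 call.

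Probes with the Wbm prefix were mostly dim. Of 804 such probes, 10 entered the tests. Their median log2 ratio was 0.25 after 3 h and -0.35 after 24 h at 37C, -0.81 at 5 days, -0.47, -0.30 and 0.21 after 3 h, 24 h and 48 h of ascorbic acid, 0.06 in molting and -0.35 in L4 larvae. Among 10000 random lists matched on brightness, these medians stood at the percentiles 77.4, 0.73, 0, 0.05, 0.12, 14.5, 29.0 and 1.55, as a description of these arrays. Relative to the median of all tested probes, the list stood at -1.05 to 0.21, below 0 on 6 of 8 arrays. With median centring it stood at -1.31 to 0.08, below 0 on 7, and in the authors' values, with 9 matched probes, at -1.24 to 0.18, below 0 on 6. The arrays differed between these scalings: at 3 h at 37C the list stood at 0.21 here and -1.24 in the authors' values, and after 48 h of ascorbic acid at 0.01 and -1.22. The median of the list had the other sign on 2 arrays with median centring and on 6 in the authors' values. None of the 10 was called in either fit, over all probes or adjusted over the list alone, and 1 had an unadjusted p under 0.05 in each fit. With camera the list had p = 0.327 for the phase difference and 0.620 for the slope at the preset correlation of 0.01. With an estimated correlation the values were p = 0.541 and p = 0.759.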

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

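The tests of the control oligonucleotides were chosen after the values were seen. The 10 control oligonucleotides, which no comparison uses, were above background in Cy5 in 88.8% of their spots, against 0.37% of the empty spots. Their median log2 ratio moved by 2.32 between arrays: 2.23 and 1.14 after 3 h and 24 h at 37C, 0.71 at 5 days, 0.56, 1.09 and 1.30 with ascorbic acid, 2.87 in molting and 2.74 in L4 larvae. For all 10, the mean over the arrays of days 5 to 7 was below the value on the first array and below the mean of the molting and L4 arrays; without normalization this held for 8.

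Within-array normalization may account for the larger part of the fall from the first array to days 5 to 7, 1.32 with it and 0.43 without it. For the rise from there to molting and L4 larvae, 1.89 and 1.30, it cannot be told apart as the main source, because the share left without it varied between the oligonucleotides. The Cy3 channel of the oligonucleotides is argued against, since it moved by 0.58. Over the 8 arrays the ratio fell as the percent of spots found rose, with r = -0.86 (exact permutation p = 0.0156, two-sided), rho = -0.71 (exact permutation p = 0.0576), r = -0.79 without the 2 farthest arrays and -0.89 within the 6 arrays of a single header date. Without normalization r was -0.70 (exact permutation p = 0.0486). Varying amounts of labelled worm cDNA against a fixed amount of control may account for this, and cannot be told apart from unequal amounts of control, because the sources used here do not state whether or how much was added. A change in messenger RNA content during culture stays open as a biological explanation, untested.

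Spots of probes with the Wbm prefix, nearly all outside the tests, were above background in Cy5 more often than empty spots on all 8 arrays. After 3 h of ascorbic acid this held for 63 of 1608 such spots and 0 of 1384 empty spots, in L4 larvae for 22 and 2, and at 3 h at 37C, where the empty spots came closest, for 53 and 29. The excess lay in 1.37% to 3.92% of the Wbm spots. Median Cy5 signal less background was -7 to 3 over the arrays for Wbm spots and -1 to 5 for empty spots, so that a typical Wbm spot did not stand out. Signal from the endosymbiont is not shown by this.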

How the results depend on the processing

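The header date as a block, the 6 arrays of a single date, probes on all 8 arrays and the quadratic day term were chosen after seeing the data. For the probes named for the phase difference and the slope, the direction held in all alternatives run except these: BMW00014.430 had a phase difference of 0.18 with the header date as a block and 0.18 within the 6 arrays of a single date, and BMW00290.540 a slope of 0.14 and 0.21. By construction both settings leave out the contrast between the first 2 arrays and the others. No paired analysis was possible because each time point has 1 array. The alternative with probes of Brugia malayi alone was not run, since probe names do not state the organism, and a list with 1 probe per gene was not run for want of gene names. Dim L3 signal limits the higher ratios: 2271 to 2991 of 18104 probes were above background in Cy3.

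The phase count of 1 became 0 with no background correction, plain subtraction, median centring, both channels above background, not-found spots kept, the authors' values, scale normalization, Cy5 alone, 3 against 3 arrays, the header date block, the 6 arrays of a single date and probes on all 8 arrays. Under the block BMX8314 has no phase test, because its arrays before and after ascorbic acid differ in date. The count ran from 0 to 5 leaving out each array, and stayed 1 with no filter and array weights. The trend count of 0 ran from 0 to 1 leaving out each array, was 43 with the header date block, 19 within 6 arrays and 45 for the quadratic term, and otherwise 0. Elsewhere the cause was not tested.

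Keeping not-found spots left all 15 counts of 2-fold changes within 1.5 times. The counts that moved further are given in the order of the time points, then of the steps. No background correction gave 307 and 797 at 3 h and 24 h, and 607, 313, 313 and 466 for the steps to 24 h, to ascorbic acid 3 h and 24 h, and to L4. Plain subtraction gave 1410, 1921 and 2306 at 3 h, 24 h and molting, and 1647, 2092, 1193, 1156, 1398, 2193 and 1477 for the steps. Median centring gave 2619 at ascorbic acid 3 h, and 1658 and 1479 for the steps to 24 h and to L4. No filter gave 1657, 2257, 2838, 3319, 2764, 2903, 2133 and 2621, and 2706, 3218, 2855, 2611, 2864, 3176 and 2172 for the steps, over more probes. Both channels above background gave 139, 305, 363, 329, 374, 371, 400 and 384, and 166, 284, 46, 90, 155, 325 and 172, over fewer probes. The authors' values gave 2010, 2976, 3828, 4054, 3309, 3614, 2565 and 3380, and 2115, 2329, 1173, 1376, 1427, 2725 and 2282. Apart from the filters, the cause was not tested.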

Other observations

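The tests of the curved and swinging courses were chosen after the results were seen, except that of weaker signal on the molting and L4 arrays. A quadratic day term in limma called 45 probes, 40 of them higher in the middle of the course. The median log2 ratio of these 40 was -0.39 and 0.07 after 3 h and 24 h at 37C, 2.78 at 5 days, 2.54, 2.62 and 2.21 with ascorbic acid, 0.23 in molting and -0.12 in L4 larvae. Cy5 was above background for 7, 13, 40, 39, 37, 38, 10 and 12 of the 40 in the order of the arrays, and Cy3 on no array for 31, so that most of these ratios are limited by the background. At BMX6940 the log2 ratio was 0.15 at 24 h, 5.35 at 5 days, 4.77 after 48 h of ascorbic acid and -0.25 in L4 larvae (adjusted p = 0.0259).

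Of 100 orders of the days, the real one included, 3 gave at least 45 calls. The highest of the others gave 170, which points to a structure of the arrays. The quadratic term was added after the data were seen, so that this count does not exclude chance order. Whether a change in the L3 reference had a part cannot be told. For the 40 probes higher in the middle, Cy5 itself differed: it was above background for 37 to 40 of them on days 5 to 7 and for 7 to 13 on the other arrays. Over the 45 called probes the Cy5 curve had a slope of 0.85 ± 0.03 (SE) on that of the ratio. By construction this slope is fixed by that of Cy3, -0.15, and it adds no separate support. Cy3 was above background on no array for 31 of the 40. The Cy3 channel alone cannot decide, since it was above background on at least 4 arrays for 5 of the 45, 2 of them higher in the middle. Over these 5 the Cy3 curve had a slope of -0.068 ± 0.037 (SE) on that of the ratio. Weaker signal on the molting and L4 arrays was predicted to lower nearly all probes at least 4-fold higher on days 5 to 7. Of 176 such probes 14.8% kept or exceeded that ratio, past the limit set, and the median moved by -1.63. The 95% exact binomial interval, 9.88% to 20.9%, treats probes as independent, which they are not. This does not decide the cause for the 40 called probes, since the 176 were chosen by their ratio. Cy5 was above background for 10 of the 40 in molting and 12 in L4 larvae. Array-wide signal may still have a part and cannot be told apart: the percent of spots found followed the quadratic term at r = -0.89 (exact permutation p = 0.0066, two-sided), rho = -0.81 (exact permutation p = 0.0218), r = -0.80 without the 2 farthest arrays and -0.86 within the 6 arrays of a single header date, and with it in the model 0 probes were called. No test here decides whether expression of these probes changed around the molt.

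Without a test, 33 of 5502 probes went down, up, down and up by at least 2-fold at each step over the first 5 arrays, against 7 with the mirrored course. Their median log2 ratio was 1.39, -0.45, 2.51, -0.17 and 1.91, then 0.66, -0.53 and -1.02 on the last 3 arrays. Spot noise is argued against, since 21 of the 33 had the course in both spots, and so is the L3 channel as the main part, whose differences followed those of the ratio at a slope of -0.25 ± 0.04 (jackknife SE) over the 22 probes with Cy3 above background on at least 4 of the 5 arrays. An exchange of the arrays of 24 h and 5 days at 37C would leave a rise, a fall and a rise, with medians of 1.39, 2.51, -0.45, -0.17 and 1.91. It is also argued against: over all tested probes the array of 3 h of ascorbic acid correlated at 0.81 with that of 5 days and at 0.58 with that of 24 h at 37C, a difference of 0.24. Exchanges of the array of 3 h of ascorbic acid with that of 5 days or of 24 h of ascorbic acid cannot be told apart from the labelled order, since the differences of r that bear on them, 0.083 and 0.032, were small. Both differences lay in the direction that an exchange would give. Larval pools that differed between time points may account for the swings, and this was not tested.

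For the phase difference, 8 of the 56 splits of the arrays into 3 and 5 called at least 1 probe, the real number, so chance cannot be excluded. The highest other count was 68, for 24 h at 37C with molting and L4 against the rest, several times the real count, which points to a structure of the arrays other than the phase. The next, 45, set the arrays of 3 h and 24 h at 37C, which share a header date, and molting against the rest; for the probe called in the real split, date and phase cannot be told apart, and with the date as a block 0 probes were called. For the slope over days, 21 of 100 orders gave at least 491 probes at an unadjusted p under 0.05, and the highest other gave 1308, so chance cannot be excluded there either. This holds for the fit without the header date. With the date as a block 15 positive and 28 negative slopes passed, and no random orders were run for that fit.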
